A study of Homo sapiens with 16 samples.

How the data were processed

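The series holds read counts per gene from 16 RNA-seq libraries of MDA-MB-231 cells in 8 groups of 2: DMSO, MMS, sorafenib and sorafenib followed by MMS, each at 8 h and 24 h. Total RNA was made into TruSeq libraries from cells in DMEM with 10% serum. The deposited values are raw counts, made by the authors from reads called with CASAVA 1.8.2, aligned to hg19 with TopHat2 2.0.8b and counted with HTSeq, per the submitters' processing notes. The annotation, the strand setting and the HTSeq version and mode are not stated in the sources used, so that reads shared by paralogs or overlapping genes cannot be traced. The MMS dose differs between the sources (40 µg/mL in the series description, 40 µM in the sample labels), and neither was chosen.

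Each file had 23228 gene rows and 5 rows that are not genes, which were kept out of library sizes and tests. Of the gene names 19425 are current, 2506 are older symbols, kept as deposited, and 1297 matched no table of names. Reads in no gene made up 6.88 to 7.94% per library, ambiguous reads 1.03 to 1.18% and reads with several alignments 29.5 to 31.5%. The 10 most abundant genes took 2.44 to 3.54% of counts. Gene names came from GENCODE v29 and RefSeq tables of a later genome build, used for names, spans and GC content only.

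Levels are given as counts per library total, scaled by TMM factors (CPM). Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter (13948 genes kept), 1 mean per group, quasi-likelihood tests and Benjamini-Hochberg adjusted p under 0.05. There were 14 comparisons: 8 between treatments within a time, 2 interactions, 3 differences of an effect between the times and DMSO at 24 h against 8 h. The p-values of the main fit measure the spread between the libraries of a group, which the series text calls independent experiments. A total of 27 gene lists were fixed beforehand and 26 tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over 208 tests). The mitochondrial list was left out, since none of its members was among the genes analysed. A count adjusted over the list alone treats the members of that list as the only genes tested.

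Genes were named by a rule: the 5 largest rises and 5 largest falls past the threshold with a mean count of at least 50 and both treated libraries on the same side of both reference libraries, up to 4 members with the smallest p of each list called by camera or with at least 2 members past the threshold, study genes past it, and IL8, IL6 and VEGFA always. For interactions and differences between times it took the 5 smallest p per direction, and with fewer than 5 it took all. The text leaves out some genes the rule names. The samples, comparisons, lists, naming rule and alternatives were chosen before the data were examined.

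Titles begin in 2 ways, once per group, and may mark the experiments. The check correlated the deviations from group means between groups: 28 pairs of groups gave 0.489 to 0.707 (median 0.638), all above 0.1, and the second principal component separated the title starts. The main fit had no block (8 residual degrees of freedom, 7 with it), and a fit with the title start as replicate block is given beside results it changed. Biological variation was 0.136 without and 0.0632 with the block. On simulated changes in the counts of sorafenib against DMSO at 8 h, the main fit recovered 49.3% of 1.5-fold changes, 85.1% at 2-fold and 98.5% at 4-fold, with 0 false calls of 158. The blocked fit recovered 85.1, 98.5 and 100%, with 8 false of 217. The changed genes all had a mean count of at least 50. Counts were drawn with the block effect and the spread of the blocked fit. Its higher recovery was therefore built in, and the simulation does not rank the 2 fits.

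Alternatives were RLE factors, DESeq2 1.42.0, no filter, a mean count of at least 50, the block, only the libraries compared, each library left out in turn, and for lists an estimated correlation and fry. A group left with 1 library was assumed to vary like the others, and it held 1 title start only. The fits without a library had no block, so that any effect of the title start entered the comparisons of that group. A call lost in them can reflect the title start or the smaller group as well as the library left out. A test for outlying samples within a group, which takes at least 4, was not run, and outlying libraries were not looked for in the whole fit.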

Results

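RNA was sequenced from MDA-MB-231 cells, a human breast cancer line that lacks the oestrogen receptor, grown in sub-confluent dishes. Cells received the solvent DMSO, the DNA-methylating agent methyl methanesulfonate (MMS), the multikinase inhibitor sorafenib at 1 µM, or sorafenib for 12 h followed by MMS, called the combination here. The MMS dose is 40 µg/mL in the series description and 40 µM in the sample labels, and both are given because they differ. RNA was taken at 8 h and 24 h, counted from the MMS addition for the combination, so that its cells had 12 h more sorafenib than cells on sorafenib alone. The 8 groups held 2 libraries each, 16 in all, from 2 independent experiments. Reads counted in genes came to between 16774156 and 26448212 per library, with a median of 20348720. Values below are means per group in normalised counts (CPM) ± SD, or log2 changes ± SE, with n = 2 libraries per group throughout. The study's title sets the question as one of inflammation and angiogenesis under a low dose of sorafenib and alkylating agents.

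The comparison of MMS with DMSO at 8 h asked what the alkylating agent alone did. Genes of the ATF4 integrated stress response, the program that cells start when translation initiation is restrained, rose together: 34 rose of 38 measured, or 34 rose adjusted over the list alone. Among them were the p53- and ATF4-responsive SESN2 (log2 change 3.05 ± 0.12 SE, adjusted p = 1.67e-07), the transcription factor ATF3 (log2 change 3.52 ± 0.23 SE, adjusted p = 1.77e-06), the pseudokinase TRIB3 (2.42 ± 0.14), the CHOP gene DDIT3 (2.10 ± 0.18) and the transcription factor CEBPG (1.55 ± 0.10). ATF3 stood at 87.8 ± 1.22 CPM against 7.62 ± 1.28 (SD, n = 2). Of the endoplasmic reticulum chaperone and unfolded protein list, 19 rose of 26 measured, or 21 rose adjusted over the list alone, led by the chaperone HSPA5, the degradation factor HERPUD1 (2.01 ± 0.12), the splicing-activated factor XBP1 (1.65 ± 0.10) and the co-chaperone DNAJB9 (1.75 ± 0.12). HSPA5 stood at 3146 ± 199 CPM against 901 ± 78.6 (SD, n = 2). Of the NRF2 and oxidative stress list, 19 rose of 27 measured, or 19 rose adjusted over the list alone, among them heme oxygenase HMOX1 (3.28 ± 0.22), thioredoxin reductase TXNRD1 (2.12 ± 0.12) and the quinone reductase NQO1 (1.75 ± 0.10). The highest adjusted p of these genes was 8.82e-06. In camera's test against other genes the ATF4, endoplasmic reticulum and NRF2 lists had adjusted p of 2.00e-35, 8.13e-17 and 8.21e-23, and 0.00894, 0.0134 and 0.00894 with an estimated correlation. 

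Further stress genes rose at 8 h. Of the p53 target list, 14 rose and 1 fell of 30 measured, or 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.68e-05). These included the growth arrest gene GADD45A (2.20 ± 0.18), the fructose bisphosphatase gene C12orf5 (0.72 ± 0.08), the cytokine GDF15 (1.78 ± 0.31), the p53 ubiquitin ligase MDM2 (0.43 ± 0.08) and the cell cycle inhibitor CDKN1A (1.49 ± 0.49, adjusted p = 0.0392). Of the immediate early list, 16 rose of 28 measured, or 17 rose adjusted over the list alone (camera adjusted p = 2.30e-09, adjusted p = 0.127 with an estimated correlation). These included EGR1 (2.69 ± 0.45), FOS (2.67 ± 0.29) and the phosphatase DUSP1 (1.95 ± 0.16). Of the heat shock list, 10 rose and 1 fell of 29 measured, or 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00046, adjusted p = 0.0575 with an estimated correlation). These included the near-identical HSPA1A (1.12 ± 0.12) and HSPA1B (0.87 ± 0.12), whose reads cannot be assigned with certainty. Of the metallothionein and metal response list, 3 rose of 7 measured, or 3 rose adjusted over the list alone (camera adjusted p = 0.0358, adjusted p = 0.133 with an estimated correlation, adjusted p = 0.0641 with the block). These included the zinc exporter SLC30A1 (1.01 ± 0.11) and the metal-sensing factor MTF1 (0.73 ± 0.12). The largest rises by the fixed rule were in the unnamed locus LOC344887 (5.28 ± 0.42), the heat shock gene HSPA6 (4.71 ± 0.74), the activity-regulated gene ARC (4.67 ± 0.51), ATF3 (3.52 ± 0.23) and the peptide hormone ADM2 (3.38 ± 0.20). ARC stood at 14.8 ± 3.62 CPM against 0.549 ± 0.341 (SD, n = 2), and the DMSO levels of LOC344887, HSPA6 and ARC were below 1 CPM, so that their folds rest on few reads. The largest falls by that rule were in the cyclic nucleotide phosphodiesterases PDE4B (-4.07 ± 0.24) and PDE7B (-3.43 ± 0.66), the Notch-modifying enzyme LFNG (-3.03 ± 0.37), the inhibitory SMAD SMAD6 (-2.95 ± 0.29) and the metalloprotease ADAMTS15 (-2.83 ± 0.23). CDKN1A did not pass without DMSO replicate 1 (adjusted p = 0.227) or without DMSO replicate 2 (adjusted p = 0.0631) or without MMS replicate 2 (adjusted p = 0.206).

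Inflammatory and angiogenic genes moved in both directions at 8 h. Of the cytokine and chemokine list, 6 rose and 7 fell of 25 measured, or 7 rose and 8 fell adjusted over the list alone. The neutrophil chemokines CXCL3 (log2 change 2.86 ± 0.27 SE, adjusted p = 1.68e-05), CXCL2 (2.35 ± 0.23) and IL8, now named CXCL8 (1.34 ± 0.23), rose, as did IL6 (0.78 ± 0.20), IL1A (0.85 ± 0.25) and the prostaglandin synthase PTGS2 (2.17 ± 0.41), while the colony-stimulating factors CSF1 (-1.87 ± 0.17) and CSF2 (-1.09 ± 0.12) fell, with adjusted p up to 0.0247. IL8 stood at 1342 ± 98.9 CPM against 531 ± 14 (SD, n = 2), and CXCL2 and CXCL3 are close paralogs that can share reads. The list as a whole had a median of 0.20 and a mean of -0.06 (camera adjusted p = 0.949). Of the NF-kB feedback list, 2 rose and 10 fell of 26 measured, or 3 rose and 11 fell adjusted over the list alone, and 6 rose and 15 fell with the block (camera adjusted p = 0.000367, adjusted p = 0.106 with an estimated correlation). These included the inhibitor NFKBIA (-1.55 ± 0.09), the caspase inhibitor family member BIRC3 (-1.70 ± 0.13) and the deubiquitinase TNFAIP3 (-0.85 ± 0.13). Of the angiogenic list, 2 rose and 12 fell of 32 measured, or 3 rose and 13 fell adjusted over the list alone, and 5 rose and 17 fell with the block (camera adjusted p = 0.000273). These included the angiogenesis inhibitor THBS1 (-1.63 ± 0.11) and the growth factors VEGFC (-1.16 ± 0.08), PDGFC (-1.01 ± 0.09) and PGF (-1.82 ± 0.24). VEGFA, the main endothelial growth factor, had a log2 change of 0.12 ± 0.18 (adjusted p = 0.671), and -0.05 without DMSO replicate 1. Of the matrix protease list, 4 rose and 5 fell of 25 measured, or 4 rose and 5 fell adjusted over the list alone, and 8 rose and 8 fell with the block (camera adjusted p = 0.673). These included stromelysin MMP3 (2.86 ± 0.40) higher and urokinase PLAU (-1.94 ± 0.24) and the protease inhibitor TIMP3 (-1.09 ± 0.11) lower. IL6 and IL1A did not pass without DMSO replicate 1 (adjusted p from 0.128 to 0.203) or without MMS replicate 2 (adjusted p from 0.12 to 0.14). IL1A did not pass without MMS replicate 1 (adjusted p = 0.0588).

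Cell cycle genes split at 8 h. Of the mitosis and G2/M list, 32 fell of 42 measured, or 35 fell adjusted over the list alone (camera adjusted p = 4.85e-19, adjusted p = 0.0644 with an estimated correlation). These included topoisomerase TOP2A (-1.55 ± 0.13), the mitotic kinase PLK1 (-1.24 ± 0.12) and the kinesin KIF20A (-1.27 ± 0.12). Of the replication and E2F list, 8 rose and 4 fell of 44 measured, or 8 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.304). These included the ribonucleotide reductase subunit RRM2 (0.90 ± 0.08) and the origin licensing factor CDC6 (0.53 ± 0.07) higher and UHRF1 (-0.71 ± 0.10) lower. Of the homologous recombination and Fanconi list, 8 rose of 37 measured, or 6 rose adjusted over the list alone, and 13 rose and 3 fell with the block (camera adjusted p = 0.191). These included BRCA2 (0.88 ± 0.15). Of the base excision repair list, 2 rose and 4 fell of 27 measured, or 4 rose and 6 fell adjusted over the list alone, and 5 rose and 8 fell with the block (camera adjusted p = 0.673). These included the glycosylase MBD4 (0.54 ± 0.08) higher and the scaffold XRCC1 (-0.52 ± 0.10) lower. Of the ERK output list, 6 rose and 8 fell of 27 measured, or 6 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.254 with an estimated correlation, adjusted p = 0.0501 with the block). These included cyclin CCND1 (-1.28 ± 0.09), the ERK phosphatase DUSP6 (-1.28 ± 0.09) and the feedback inhibitor SPRY1 (-2.36 ± 0.18) lower. Of the TGF-beta and mesenchymal list, 1 rose and 6 fell of 31 measured, or 1 rose and 11 fell adjusted over the list alone, and 3 rose and 19 fell with the block (camera adjusted p = 0.000406, adjusted p = 0.123 with an estimated correlation). These included SMAD3 (-1.62 ± 0.10) and TGFBR2 (-1.23 ± 0.14) lower. Of the interferon list, 7 fell of 32 measured, or 6 fell adjusted over the list alone, and 3 rose and 11 fell with the block (camera adjusted p = 0.0343, adjusted p = 0.427 with an estimated correlation, adjusted p = 0.066 with the block). These included IRF1 (-1.16 ± 0.10). Of the hypoxia and glycolysis list, 4 rose and 5 fell of 32 measured, or 4 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.345). Of the apoptosis list, 7 rose and 4 fell of 29 measured, or 9 rose and 6 fell adjusted over the list alone, and 12 rose and 6 fell with the block (camera adjusted p = 0.985). Of the cholesterol list, 2 rose and 3 fell of 26 measured, or 1 rose and 3 fell adjusted over the list alone, and 6 rose and 7 fell with the block (camera adjusted p = 0.866). Of the luminal epithelium markers, 1 rose and 4 fell of 16 measured, or 1 rose and 4 fell adjusted over the list alone, and 1 rose and 7 fell with the block (camera adjusted p = 0.51). These included KRT18 (-0.47 ± 0.10) and ELF3 (-2.55 ± 0.57) lower. Of the fibroblast and endothelial markers, 3 fell of 8 measured, or 5 fell adjusted over the list alone, and 6 fell with the block (camera adjusted p = 0.0542). These were PECAM1 (-1.52 ± 0.32), KDR (-0.78 ± 0.22) and COL1A1 (-0.72 ± 0.22). In all, 3694 of 13948 genes passed edgeR's test, 2024 higher and 1670 lower, and 6035 with the replicate block. The count was 2272 without DMSO replicate 1, 2448 without MMS replicate 1 and 2432 without MMS replicate 2. KRT18, KDR and COL1A1 did not pass without DMSO replicate 1 (adjusted p from 0.0584 to 0.15). KRT18, ELF3 and COL1A1 did not pass without MMS replicate 2 (adjusted p from 0.0521 to 0.119). KDR and COL1A1 did not pass without MMS replicate 1 (adjusted p from 0.112 to 0.143) or without DMSO replicate 2 (adjusted p from 0.0604 to 0.0668). Camera called 13 of the 26 lists, and 5 of these also with an estimated correlation.

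**Figure D1:**
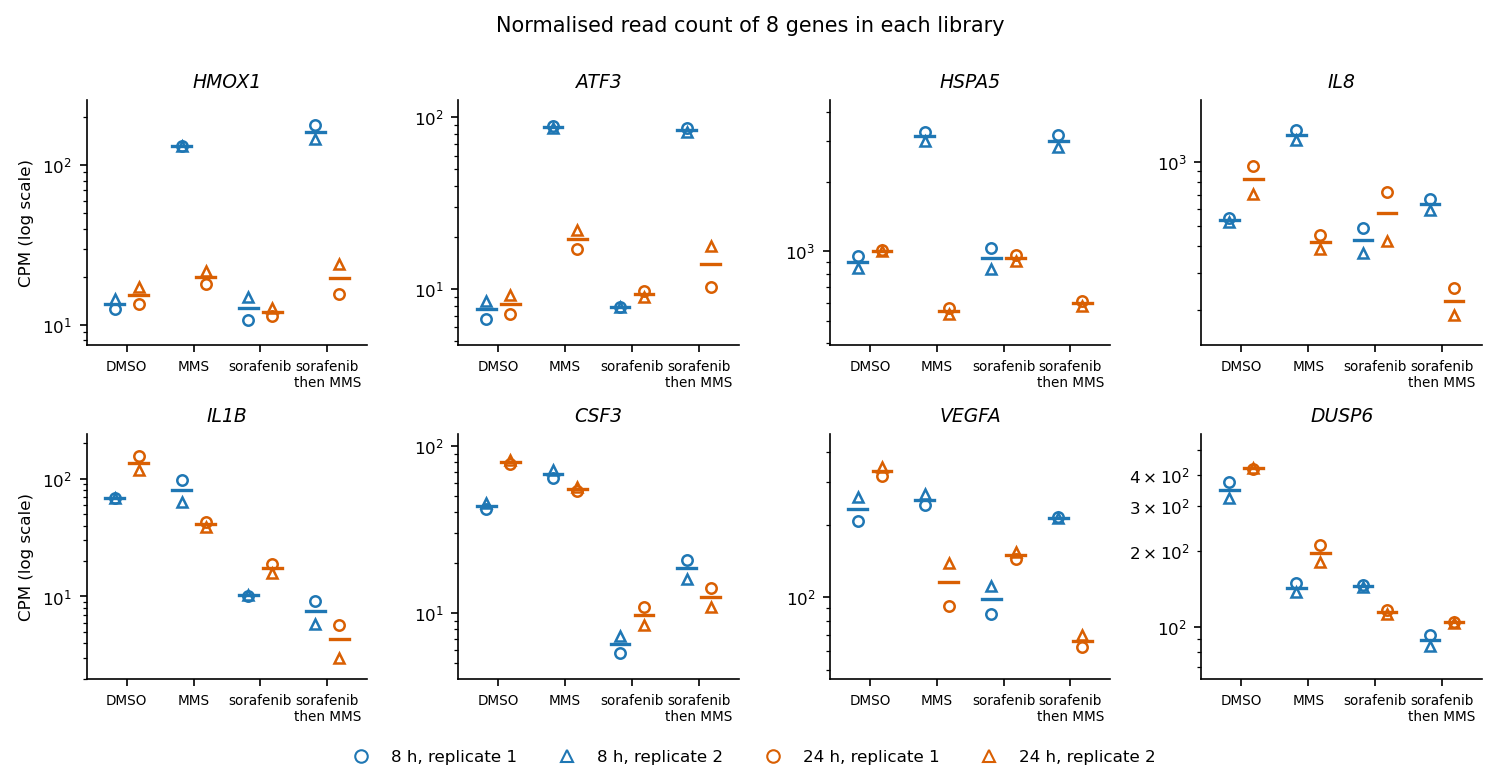
Normalised read count (CPM, log scale) of 8 genes in each of the 16 libraries, by treatment, with circles for replicate 1, triangles for replicate 2, blue for 8 h, orange for 24 h and a bar at the mean of each group. HSPA5 with MMS stood at 3146 CPM against 901 at 8 h and 552 CPM against 1004 at 24 h, while IL1B and CSF3 were lower in every sorafenib library than in every DMSO library of the same time.

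At 24 h after MMS part of the endoplasmic reticulum and inflammatory genes stood below DMSO. Of the endoplasmic reticulum list, 2 rose and 11 fell of 26 measured, or 2 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.222 with an estimated correlation). These included HSPA5 (log2 change -0.86 ± 0.11 SE, adjusted p = 0.000155), the transport coat gene SEC24D (-1.13 ± 0.09) and the chaperone HSP90B1 (-0.55 ± 0.09). Of the cytokine list, 11 fell of 25 measured, or 14 fell adjusted over the list alone, and 18 fell with the block (camera adjusted p = 1.42e-07, adjusted p = 0.0634 with an estimated correlation). These included CSF1 (log2 change -2.51 ± 0.17 SE, adjusted p = 4.42e-06), IL1B (-1.75 ± 0.25), IL1A (-1.33 ± 0.26), the death ligand TNFSF10 (-2.22 ± 0.25), IL8 (-0.99 ± 0.23) and IL6 (-0.77 ± 0.20). In the angiogenic list, 2 rose and 11 fell of 32 measured, or 2 rose and 13 fell adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.0634 with an estimated correlation). These included VEGFA (log2 change -1.53 ± 0.18 SE, adjusted p = 0.000126) and VEGFC (-0.50 ± 0.08), and endothelin EDN1 rose, to 118 CPM against 41.7. VEGFA stood at 115 ± 33.2 CPM against 333 ± 21.2 (SD, n = 2). Of the hypoxia and glycolysis list, 1 rose and 17 fell of 32 measured, or 1 rose and 22 fell adjusted over the list alone (camera adjusted p = 9.37e-08, adjusted p = 0.127 with an estimated correlation). These included lactate dehydrogenase LDHA (-0.89 ± 0.07), the glucose transporter SLC2A1 (-0.76 ± 0.10) and the mTORC1 inhibitor DDIT4 (-2.44 ± 0.22). Of the NF-kB list, 12 fell of 26 measured, or 13 fell adjusted over the list alone (camera adjusted p = 0.000497, adjusted p = 0.106 with an estimated correlation). Of the matrix protease list, 3 rose and 12 fell of 25 measured, or 4 rose and 14 fell adjusted over the list alone, and 9 rose and 16 fell with the block (camera adjusted p = 0.00016, adjusted p = 0.127 with an estimated correlation). These included MMP3 (3.52 ± 0.42) higher and TIMP3 (-1.99 ± 0.11) and LOXL2 (-1.72 ± 0.09) lower. Of the interferon list, 14 fell of 32 measured, or 15 fell adjusted over the list alone (camera adjusted p = 5.32e-05, adjusted p = 0.123 with an estimated correlation). These included IFIT2 (-1.60 ± 0.14). Of the TGF-beta list, 1 rose and 13 fell of 31 measured, or 1 rose and 14 fell adjusted over the list alone, and 3 rose and 19 fell with the block (camera adjusted p = 2.45e-05, adjusted p = 0.0755 with an estimated correlation). These included collagen COL5A1 (-2.01 ± 0.15). The highest adjusted p of the genes named here was 0.0117. IL8 did not pass without DMSO replicate 1 (adjusted p = 0.0625) or without MMS replicate 2 (adjusted p = 0.0645). IL6 did not pass without MMS replicate 1 (adjusted p = 0.117) or without DMSO replicate 2 (adjusted p = 0.0544).

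Part of the recombination, replication and redox genes stood above DMSO at 24 h. Of the homologous recombination list, 20 rose of 37 measured, or 20 rose adjusted over the list alone (camera adjusted p = 2.90e-05, adjusted p = 0.277 with an estimated correlation). These included XRCC3 (log2 change 0.92 ± 0.10 SE, adjusted p = 6.07e-05), RAD51AP1 (0.63 ± 0.08) and RAD51C (0.77 ± 0.12). Of the replication list, 20 rose and 6 fell of 44 measured, or 21 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.000311, adjusted p = 0.379 with an estimated correlation). These included RRM2 (log2 change 1.03 ± 0.08 SE, adjusted p = 1.25e-05) and CDT1 (0.90 ± 0.12). Of the NRF2 list, 11 rose and 2 fell of 27 measured, or 12 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.000105, adjusted p = 0.149 with an estimated correlation). These included NQO1 (log2 change 1.72 ± 0.10 SE, adjusted p = 2.69e-06) and ferritin FTL (1.69 ± 0.15) higher and the transporter ABCC3 (-2.59 ± 0.29) lower. Of the ATF4 list, 15 rose and 5 fell of 38 measured, or 16 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.515 with an estimated correlation). These included the amino acid transporter subunit SLC3A2 (1.15 ± 0.13) higher. Of the heat shock list, 7 rose and 2 fell of 29 measured, or 7 rose and 2 fell adjusted over the list alone, and 14 rose and 2 fell with the block (camera adjusted p = 0.0208, adjusted p = 0.134 with an estimated correlation). Of the mitosis list, 1 rose and 27 fell of 42 measured, or 2 rose and 30 fell adjusted over the list alone (camera adjusted p = 1.44e-10, adjusted p = 0.136 with an estimated correlation). These included KIF20A (-1.30 ± 0.12) and PLK1 (-0.97 ± 0.12). Of the ERK list, 5 rose and 10 fell of 27 measured, or 5 rose and 13 fell adjusted over the list alone (camera adjusted p = 0.000367, adjusted p = 0.127 with an estimated correlation). These included DUSP4 (-1.01 ± 0.07) and DUSP6 (-1.11 ± 0.09) lower. Of the immediate early list, 7 rose and 2 fell of 28 measured, or 7 rose and 2 fell adjusted over the list alone, and 12 rose and 3 fell with the block (camera adjusted p = 0.029, adjusted p = 0.577 with an estimated correlation). Of the p53 list, 7 rose and 3 fell of 30 measured, or 8 rose and 4 fell adjusted over the list alone, and 12 rose and 7 fell with the block (camera adjusted p = 0.41). These included GDF15 (-1.99 ± 0.32) lower. Of the apoptosis list, 3 rose and 10 fell of 29 measured, or 4 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.32). Of the base excision repair list, 8 rose and 4 fell of 27 measured, or 8 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.104). Of the cholesterol list, 2 rose and 7 fell of 26 measured, or 2 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.145). Of the metallothionein list, 3 fell of 7 measured, or 3 fell adjusted over the list alone (camera adjusted p = 0.145). By the fixed rule, with its limits on counts and separation, the largest rises were in ARC (5.09 ± 0.57), HSPA6 (4.36 ± 0.71) and MMP3 (3.52 ± 0.42), and the largest falls in the secreted protein AGR2 (-4.61 ± 1.40), the NADPH oxidase NOX5 (-4.56 ± 0.43) and the hyaluronidase KIAA1199, now CEMIP (-4.43 ± 0.30). The folds of ARC, at 8.82 ± 0.0592 CPM against 0.254 ± 0.280 (SD, n = 2), and HSPA6, at 5.90 ± 2.66 CPM against 0.282 ± 0.320 (SD, n = 2), rest on few DMSO reads. AGR2 was at -3.87 without DMSO replicate 1, -5.76 without MMS replicate 1 and -3.83 without MMS replicate 2, and it did not pass in these fits. These fits cannot tell a library from the title start.

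Markers of other cell types were among the genes that fell at 24 h. Of the luminal epithelium markers, 8 fell of 16 measured, or 8 fell adjusted over the list alone (camera adjusted p = 0.000582). These included the factor SPDEF (-2.65 ± 0.26), at 16.1 CPM against 101. Of the fibroblast and endothelial markers, 5 fell of 8 measured, or 5 fell adjusted over the list alone (camera adjusted p = 0.00418, adjusted p = 0.106 with an estimated correlation). These included PECAM1 (-2.88 ± 0.32), at 0.841 ± 0.305 CPM against 6.35 ± 0.614 (SD, n = 2). Of the leukocyte markers, 1 fell of 5 measured, or 1 fell adjusted over the list alone, and 4 fell with the block (camera adjusted p = 0.335, adjusted p = 0.00903 with the block). Ribosomal protein genes, with 1 rose and 1 fell of 50 measured, or 1 fell adjusted over the list alone, and 1 rose and 3 fell with the block, had camera adjusted p = 0.866. The replication-dependent histone list of 14 measured genes had a median log2 change of -0.03 (camera adjusted p = 0.897). In all, 4394 genes passed, 2117 higher and 2277 lower, and 6730 with the block. Of changes over 2-fold, 134 were rises and 840 falls. The count was 2466 without MMS replicate 1. Camera called 18 of the 26 lists, of which the luminal markers alone were also called with an estimated correlation (adjusted p = 0.0427).

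The effect of MMS differed between 24 h and 8 h for 1273 genes, 492 with a higher and 781 with a lower log2 change at 24 h (3562 with the block). Stress genes had the smallest p among the lower: HSPA5 (log2 change -2.67 ± 0.15 SE, adjusted p = 7.09e-06), SESN2 (-2.85 ± 0.17), XBP1 (-2.21 ± 0.14), HERPUD1 (-2.70 ± 0.17) and DDIT4 (-3.73 ± 0.30). On the other side were the repressor ZNF238, now ZBTB18 (1.67 ± 0.12), THBS1 (1.59 ± 0.15), the RAB5 exchange factor RIN2 (1.46 ± 0.13), the kinetochore gene SPC24 (1.79 ± 0.18) and SLC45A3 (1.52 ± 0.16), with a highest adjusted p of 0.000321. In DMSO the mean level of DDIT4 was higher and that of THBS1 lower at 24 h than at 8 h, which adds to their differences. Across all genes the effects at the 2 times had a correlation of 0.55, genes not being independent replicates. Of the 3694 genes called at 8 h, 3111 had the same direction at 24 h. Called at both times were 911 higher and 956 lower, where independent lists would share 307 and 273, and 127 in opposite directions. The count of 1273 was 577 without DMSO 8 h replicate 1, 775 without MMS 8 h replicate 1, 580 without MMS 24 h replicate 1 and 643 without MMS 8 h replicate 2. 

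**Figure D2:**
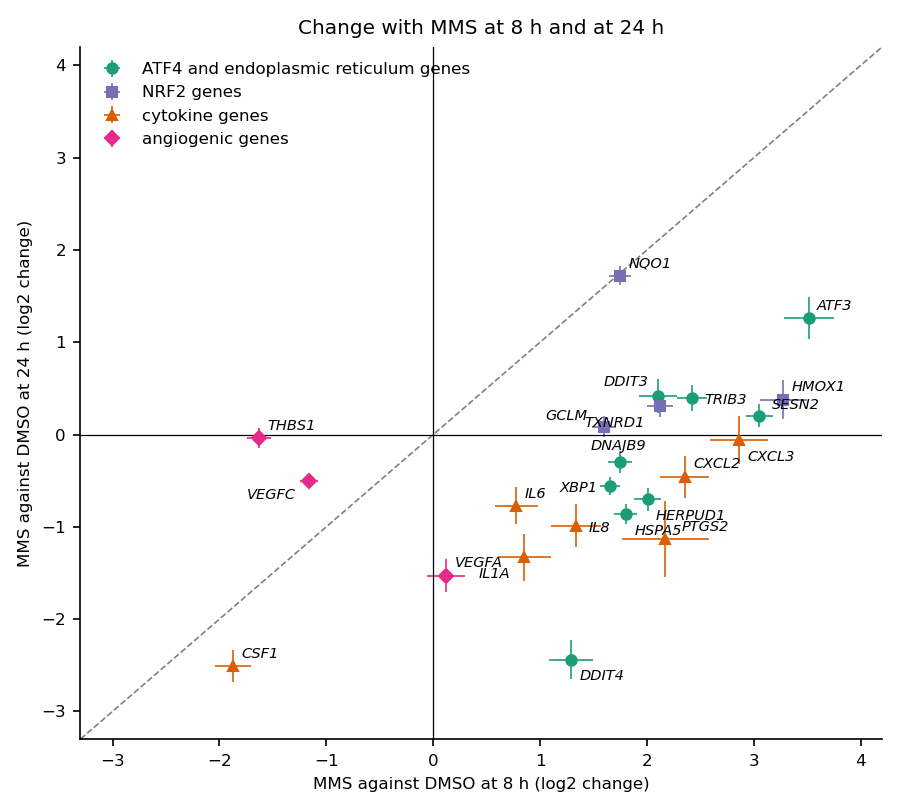
Log2 change with MMS against DMSO at 8 h (horizontal axis) and at 24 h (vertical axis) of 23 stress, redox, cytokine and angiogenic genes, with bars of 1 SE each way and the dashed line where both are equal. NQO1 lies near the line (1.75 and 1.72), HSPA5 and IL8 are above 0 at 8 h and below 0 at 24 h, and VEGFA is at 0.12 at 8 h and at -1.53 at 24 h.

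Sorafenib alone at 8 h lowered part of the outputs of the ERK pathway, which lies downstream of its RAF target, and part of the inflammatory cytokines. Of the ERK output list, 6 fell of 27 measured, or 16 fell adjusted over the list alone, and 16 fell with the block (camera adjusted p = 7.90e-44). These included the phosphatases DUSP6 (log2 change -1.25 ± 0.09 SE, adjusted p = 6.20e-05) and DUSP4 (log2 change -1.04 ± 0.07 SE, adjusted p = 2.73e-05), the feedback inhibitor SPRY4 (-0.91 ± 0.11) and the factor ETV1 (-0.89 ± 0.13). In the cytokine list, 5 fell of 25 measured, or 6 fell adjusted over the list alone, and 8 fell with the block (camera adjusted p = 3.08e-18). These included granulocyte colony-stimulating factor CSF3 (log2 change -2.75 ± 0.18 SE, adjusted p = 2.73e-05), IL1B (log2 change -2.74 ± 0.27 SE, adjusted p = 0.00119), TNFSF15 (-2.02 ± 0.26) and IL1A (-1.91 ± 0.27). CSF3 stood at 6.51 ± 1.10 CPM against 43.7 ± 2.42 (SD, n = 2). Of the angiogenic list, 2 fell of 32 measured, or 4 fell adjusted over the list alone, and 10 fell with the block (camera adjusted p = 2.70e-05). These included VEGFA (log2 change -1.25 ± 0.18 SE, adjusted p = 0.0125) and HBEGF (-0.45 ± 0.08). Of the protease list, 2 fell of 25 measured, or 11 fell adjusted over the list alone, and 1 rose and 12 fell with the block (camera adjusted p = 9.45e-12). These included TIMP3 (-0.66 ± 0.11) and tissue plasminogen activator PLAT (-1.09 ± 0.19). NOX5 (-3.20 ± 0.40) and FOS (-2.08 ± 0.34) also fell. Rises were seen for the inhibitor of differentiation ID3 (1.42 ± 0.25), TGFB2 (0.78 ± 0.13), the actin-binding NEXN (0.76 ± 0.09), the phosphatase DUSP8 (1.28 ± 0.24) and the receptor GPR1, now CMKLR2 (1.07 ± 0.17), and the highest adjusted p of the named genes was 0.0458. IL8 (-0.31 ± 0.23, adjusted p = 0.949) and IL6 (-0.14 ± 0.20, adjusted p = 1) did not pass, and IL6 was at 0.00 without DMSO replicate 2. Camera also called the immediate early (camera adjusted p = 7.45e-08, adjusted p = 0.143 with an estimated correlation) and hypoxia lists (camera adjusted p = 0.0312, adjusted p = 0.516 with an estimated correlation) lower, and the cholesterol (camera adjusted p = 3.77e-07, adjusted p = 0.133 with an estimated correlation), replication (camera adjusted p = 0.00281, adjusted p = 0.495 with an estimated correlation) and mitosis lists (camera adjusted p = 0.00856, adjusted p = 0.577 with an estimated correlation) higher. The NF-kB list had camera adjusted p = 0.177, adjusted p = 0.039 with the block.

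Of all genes 55 passed at 8 h, 16 higher and 39 lower, and 702 with the block. With only the 4 libraries compared 4 passed, with DESeq2 176 and without a filter on low counts 101. Leaving out a library gave 12 (without DMSO replicate 1), 5 (without sorafenib replicate 1), 14 (without DMSO replicate 2) and 17 (without sorafenib replicate 2). Of 21 named genes past the test, CSF3, IL1B, DUSP4 and DUSP6 passed without each library in turn. ETV1, HBEGF, TIMP3, PLAT, FOS, ID3, TGFB2, NEXN, DUSP8 and GPR1 did not pass without DMSO replicate 1 (adjusted p from 0.051 to 0.266). SPRY4, ETV1, TNFSF15, IL1A, VEGFA, HBEGF, TIMP3, PLAT, NOX5, FOS, ID3, TGFB2, NEXN, DUSP8 and GPR1 did not pass without sorafenib replicate 1 (adjusted p from 0.0917 to 0.542). TNFSF15, IL1A, VEGFA, HBEGF, TIMP3, PLAT, FOS, ID3, TGFB2, DUSP8 and GPR1 did not pass without DMSO replicate 2 (adjusted p from 0.062 to 0.399). ETV1, HBEGF, TIMP3, PLAT, FOS, ID3, TGFB2, DUSP8 and GPR1 did not pass without sorafenib replicate 2 (adjusted p from 0.0732 to 0.175).

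At 24 h of sorafenib part of the ERK outputs and cytokines were again lower than in DMSO. In the ERK list, 10 fell of 27 measured, or 23 fell adjusted over the list alone, and 21 fell with the block (camera adjusted p = 1.41e-62). These included DUSP6 (log2 change -1.88 ± 0.10 SE, adjusted p = 2.12e-06), SPRY4 (-1.19 ± 0.11) and DUSP4 (-0.97 ± 0.07). Of the cytokine list, 7 fell of 25 measured, or 8 fell adjusted over the list alone, and 1 rose and 10 fell with the block (camera adjusted p = 2.39e-18). These included CSF3 (log2 change -3.03 ± 0.17 SE, adjusted p = 4.27e-06), IL1B (-2.97 ± 0.27), IL1A (-2.53 ± 0.27), LIF (-0.69 ± 0.08) and CSF2 (-0.74 ± 0.11). IL1B stood at 17.5 ± 2.22 CPM against 137 ± 27.2 (SD, n = 2). In the angiogenic list, 4 fell of 32 measured, or 9 fell adjusted over the list alone, and 10 fell with the block (camera adjusted p = 2.83e-08). These included HBEGF (-0.85 ± 0.08), VEGFA (-1.16 ± 0.18, adjusted p = 0.0101), the Notch ligand JAG1 (-1.02 ± 0.18) and the matricellular factor CTGF, now CCN2 (-0.75 ± 0.15). In the protease list, 5 fell of 25 measured, or 1 rose and 11 fell adjusted over the list alone, and 2 rose and 13 fell with the block (camera adjusted p = 4.95e-13). These included collagenase MMP1 (-2.86 ± 0.47), PLAT (-1.17 ± 0.19) and TIMP3 (-0.77 ± 0.11). Of the metallothionein list, 2 fell of 7 measured, or 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.131 with an estimated correlation, adjusted p = 0.0685 with the block). These included MT1X (-0.75 ± 0.14) and MT2A (-0.62 ± 0.12), members of a family with similar sequences. Of the fibroblast and endothelial markers, 1 rose and 1 fell of 8 measured, or 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.478), LUM (1.98 ± 0.35) higher and PECAM1 (-1.53 ± 0.30) lower. Epithelial cadherin CDH1 (2.91 ± 0.58) rose, to 6.75 CPM against 0.897, with KIAA1199 (1.64 ± 0.23), ID3 (1.42 ± 0.26), TGFB2 (1.02 ± 0.14) and the transcription factor ATOH8 (2.69 ± 0.41), and the highest adjusted p of the named genes was 0.0402. IL8 (-0.54 ± 0.23, adjusted p = 0.496, and 0.00365 with the block) and IL6 (0.13 ± 0.20, adjusted p = 0.965, -0.12 without sorafenib replicate 1) did not pass. Lower by camera were also the immediate early (camera adjusted p = 0.00016, adjusted p = 0.305 with an estimated correlation), hypoxia (camera adjusted p = 0.000795, adjusted p = 0.3 with an estimated correlation) and ribosomal protein lists (camera adjusted p = 0.000754, adjusted p = 0.705 with an estimated correlation), and higher the mitosis (camera adjusted p = 1.38e-07, adjusted p = 0.227 with an estimated correlation), cholesterol (camera adjusted p = 5.93e-07, adjusted p = 0.133 with an estimated correlation) and interferon lists (camera adjusted p = 6.86e-05, adjusted p = 0.133 with an estimated correlation). The NF-kB list had camera adjusted p = 0.156, adjusted p = 0.0207 with the block, and the leukocyte markers camera adjusted p = 0.475, adjusted p = 0.00755 with the block.

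At 24 h 114 genes passed, 34 higher and 80 lower, 1001 with the block, 5 with only the 4 libraries compared and 296 with DESeq2. The count was 56 without DMSO replicate 1, 12 without sorafenib replicate 1, 31 without DMSO replicate 2 and 75 without sorafenib replicate 2. Of 33 named genes past the test, CSF3, IL1B, IL1A, HBEGF, DUSP6, DUSP4 and SPRY4 passed without each library in turn. CSF2, JAG1, CTGF, TIMP3, MT1X, MT2A, CDH1, KIAA1199, ID3, LUM and PECAM1 did not pass without DMSO replicate 1 (adjusted p from 0.0617 to 0.21). LIF, CSF2, VEGFA, JAG1, CTGF, MMP1, PLAT, TIMP3, MT1X, MT2A, CDH1, KIAA1199, ID3, TGFB2, ATOH8, LUM and PECAM1 did not pass without sorafenib replicate 1 (adjusted p from 0.071 to 0.47). CSF2, VEGFA, JAG1, CTGF, MMP1, PLAT, MT1X, MT2A, CDH1, ID3, TGFB2, ATOH8, LUM and PECAM1 did not pass without DMSO replicate 2 (adjusted p from 0.0677 to 0.358). CSF2, VEGFA, JAG1, CTGF, MT2A, ID3, LUM and PECAM1 did not pass without sorafenib replicate 2 (adjusted p from 0.056 to 0.136). All 55 genes called at 8 h had the same direction at 24 h, and the correlation of both effects across genes was 0.57. A test of the difference between the times called 0 genes with edgeR, 150 at an unadjusted p under 0.05, 0 with the block and 0 with DESeq2.

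The combination against DMSO at 8 h showed most ATF4 genes high and part of the cytokine genes low. Of the ATF4 list, 34 rose of 38 measured, or 36 rose adjusted over the list alone, with SESN2 (log2 change 3.09 ± 0.12 SE, adjusted p = 1.51e-07), TRIB3 (2.71 ± 0.14) and DDIT3 (2.33 ± 0.18). Of the NRF2 list, 18 rose of 27 measured, or 20 rose adjusted over the list alone, with HMOX1 (3.57 ± 0.22). Of the endoplasmic reticulum list, 17 rose of 26 measured, or 20 rose and 1 fell adjusted over the list alone, with HSPA5 (1.74 ± 0.11). In the cytokine list, 2 rose and 12 fell of 25 measured, or 2 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.000229, adjusted p = 0.136 with an estimated correlation). These included IL1B (log2 change -3.19 ± 0.29 SE, adjusted p = 1.39e-05), CSF3 (-1.24 ± 0.16) and CSF2 (-1.76 ± 0.12) lower and CXCL2 (1.36 ± 0.23) higher. Of the ERK list, 2 rose and 16 fell of 27 measured, or 4 rose and 18 fell adjusted over the list alone (camera adjusted p = 3.65e-13). These included DUSP6 (-1.97 ± 0.10) and DUSP4 (-1.40 ± 0.07). Of the angiogenic list, 2 rose and 14 fell of 32 measured, or 2 rose and 15 fell adjusted over the list alone (camera adjusted p = 7.77e-07). These included THBS1 (-1.83 ± 0.11) and HBEGF (-0.96 ± 0.08). IL8 (0.25 ± 0.23, adjusted p = 0.491), IL6 (0.35 ± 0.20, adjusted p = 0.247) and VEGFA (-0.13 ± 0.18, adjusted p = 0.676, 0.05 without DMSO replicate 2) did not pass. In the mitosis list, 32 fell of 42 measured, or 34 fell adjusted over the list alone (camera adjusted p = 2.59e-20, adjusted p = 0.0614 with an estimated correlation). Of the p53 list, 8 rose and 1 fell of 30 measured, or 9 rose and 2 fell adjusted over the list alone, and 12 rose and 2 fell with the block (camera adjusted p = 5.97e-05). In the NF-kB list, 1 rose and 9 fell of 26 measured, or 2 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.000273, adjusted p = 0.106 with an estimated correlation). Of the protease list, 10 fell of 25 measured, or 10 fell adjusted over the list alone (camera adjusted p = 0.000189, adjusted p = 0.127 with an estimated correlation). Of the immediate early list, 6 rose of 28 measured, or 5 rose adjusted over the list alone, and 13 rose and 3 fell with the block (camera adjusted p = 0.0102, adjusted p = 0.515 with an estimated correlation). Of the heat shock list, 10 rose of 29 measured, or 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000762, adjusted p = 0.0634 with an estimated correlation). In the replication list, 11 rose and 2 fell of 44 measured, or 12 rose and 2 fell adjusted over the list alone, and 19 rose and 3 fell with the block (camera adjusted p = 0.00399, adjusted p = 0.515 with an estimated correlation). Of the TGF-beta list, 2 rose and 7 fell of 31 measured, or 2 rose and 7 fell adjusted over the list alone, and 3 rose and 19 fell with the block (camera adjusted p = 0.00103, adjusted p = 0.133 with an estimated correlation). Of the fibroblast and endothelial markers, 2 fell of 8 measured, or 2 fell adjusted over the list alone (camera adjusted p = 0.264), PECAM1 (-2.22 ± 0.34) and KDR (-0.73 ± 0.22). In all 3389 genes passed, 1739 higher and 1650 lower, and 5514 with the block. The count was 2121 without DMSO replicate 1 and 2187 without combination replicate 1. KDR did not pass without DMSO replicate 1 (adjusted p = 0.104) or without combination replicate 1 (adjusted p = 0.153) or without DMSO replicate 2 (adjusted p = 0.0924). Camera called 14 lists, 6 of them also with an estimated correlation: the ATF4 (adjusted p = 0.00794), NRF2 (0.00894), endoplasmic reticulum (0.0184), angiogenic (0.00823), ERK (0.0108) and p53 lists (0.0272).

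Against DMSO at 24 h the combination lowered most cytokine genes and part of the angiogenic and ERK output genes. Of the cytokine list, 18 fell of 25 measured, or 20 fell adjusted over the list alone (camera adjusted p = 7.60e-18). These included IL1B (log2 change -4.96 ± 0.30 SE, adjusted p = 1.57e-06), IL1A (-3.53 ± 0.29), CSF3 (-2.67 ± 0.17), IL8 (-1.91 ± 0.24) and IL6 (-1.29 ± 0.20). IL8 stood at 221 ± 45.6 CPM against 829.8 ± 182 (SD, n = 2). In the angiogenic list, 1 rose and 12 fell of 32 measured, or 1 rose and 14 fell adjusted over the list alone, and 1 rose and 21 fell with the block (camera adjusted p = 6.86e-05). These included VEGFA (log2 change -2.33 ± 0.19 SE, adjusted p = 9.01e-06), the co-receptor NRP1 (-1.35 ± 0.19) and HBEGF (-0.92 ± 0.08). In the ERK list, 3 rose and 16 fell of 27 measured, or 3 rose and 17 fell adjusted over the list alone (camera adjusted p = 3.19e-14). These included DUSP4 (-1.99 ± 0.07) and DUSP6 (-2.02 ± 0.10). In the protease list, 2 rose and 15 fell of 25 measured, or 3 rose and 15 fell adjusted over the list alone (camera adjusted p = 3.72e-08). These included PLAT (-2.52 ± 0.20). Of the metallothionein list, 4 fell of 7 measured, or 4 fell adjusted over the list alone (camera adjusted p = 0.00118). These included MT2A (-1.30 ± 0.12). Rises by the fixed rule included ID3 (2.40 ± 0.26), the stress protein NUPR1 (2.25 ± 0.27) and IGFBP3 (2.17 ± 0.32), and falls NOX5 (-5.32 ± 0.45) and the transporter SLCO4A1 (-5.14 ± 0.54). ASB2 also fell, to 0.0183 ± 0.0258 CPM against 6.82 ± 0.771 (SD, n = 2), and with 1 of its 2 libraries at 0 the size of its fold stays open. Of the homologous recombination list, 19 rose of 37 measured, or 19 rose adjusted over the list alone (camera adjusted p = 1.81e-05, adjusted p = 0.269 with an estimated correlation). Of the replication list, 18 rose and 6 fell of 44 measured, or 20 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.000273, adjusted p = 0.378 with an estimated correlation). Of the mitosis list, 2 rose and 25 fell of 42 measured, or 2 rose and 28 fell adjusted over the list alone (camera adjusted p = 3.57e-08, adjusted p = 0.21 with an estimated correlation). Of the hypoxia list, 1 rose and 17 fell of 32 measured, or 1 rose and 20 fell adjusted over the list alone (camera adjusted p = 2.82e-07, adjusted p = 0.133 with an estimated correlation). Of the endoplasmic reticulum list, 3 rose and 11 fell of 26 measured, or 3 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.379 with an estimated correlation, adjusted p = 0.06 with the block). Of the ATF4 list, 14 rose and 6 fell of 38 measured, or 14 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.0391, adjusted p = 0.577 with an estimated correlation). Of the NRF2 list, 11 rose and 3 fell of 27 measured, or 12 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.000105, adjusted p = 0.149 with an estimated correlation). Of the luminal markers, 7 fell of 16 measured, or 7 fell adjusted over the list alone (camera adjusted p = 0.0164, adjusted p = 0.134 with an estimated correlation). Of the fibroblast and endothelial markers, 4 fell of 8 measured, or 4 fell adjusted over the list alone (camera adjusted p = 0.0295, adjusted p = 0.173 with an estimated correlation). Of the leukocyte markers, 1 fell of 5 measured, or 1 fell adjusted over the list alone, and 4 fell with the block (camera adjusted p = 0.294, adjusted p = 0.00357 with the block). In the NF-kB list, 12 fell of 26 measured, or 1 rose and 14 fell adjusted over the list alone (camera adjusted p = 0.000647, adjusted p = 0.11 with an estimated correlation). In the heat shock list, 10 rose and 2 fell of 29 measured, or 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00503, adjusted p = 0.104 with an estimated correlation). In the interferon list, 2 rose and 12 fell of 32 measured, or 2 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.00396, adjusted p = 0.269 with an estimated correlation). In the TGF-beta list, 2 rose and 14 fell of 31 measured, or 2 rose and 14 fell adjusted over the list alone (camera adjusted p = 0.000171, adjusted p = 0.106 with an estimated correlation). Camera called 18 lists, 5 higher and 13 lower, and 5 of them also with an estimated correlation: the cytokine (adjusted p = 0.00894), ERK (0.00986), angiogenic (0.0118), protease (0.043) and metallothionein lists (0.043). In all 4663 genes passed, 2262 higher and 2401 lower, and 7043 with the block, and 2940 without combination replicate 2. The highest adjusted p of the genes named was 0.000566.

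The combination's effect differed between 24 h and 8 h for 1507 genes, 626 with a higher and 881 with a lower log2 change at 24 h (4016 with the block). The smallest p among the lower belonged to SESN2 (log2 change -3.02 ± 0.17 SE, adjusted p = 4.33e-06), XBP1 (-2.32 ± 0.14), HERPUD1 (-2.90 ± 0.17), HSPA5 (-2.49 ± 0.15) and DDIT4 (-4.77 ± 0.30), and among the higher to ZNF238 (1.37 ± 0.12), STARD13 (1.18 ± 0.11), THBS1 (1.53 ± 0.15), MYBL1 (1.21 ± 0.13) and CSF2 (1.39 ± 0.16). Here too DMSO gave most of the THBS1 and part of the DDIT4 difference. The count was 646 without DMSO 8 h replicate 1, 885 without combination 8 h replicate 1, 830 without combination 24 h replicate 1, 926 without DMSO 8 h replicate 2, 765 without DMSO 24 h replicate 2 and 614 without combination 24 h replicate 2. MMS and the combination, set against the same DMSO libraries, shared 1405 rises and 1160 falls at 8 h and 1775 and 1945 at 24 h. Independent lists would share 252 and 198 at 8 h and 343 and 392 at 24 h. Groups simulated without effect shared 0 in 20 draws. With no gene changed hardly any call could arise there, so this 0 does not show how many shared calls come from the common DMSO libraries. Opposite calls numbered 4 at 8 h (29 with the block), and at 24 h edgeR gave 0 (10 with the block). The correlation of fold changes was 0.81 and 0.90 against 0.50 and 0.52 simulated. The covariance was 0.293 and 0.455 against 0.0711 and 0.072 simulated, a difference of 0.222 and 0.383. The 2 DMSO libraries per time were not split between the comparisons, which would leave each with 1, and part of the excess in shared calls and correlation may come from them. The difference of covariances leaves out the simulated part of the shared controls. The simulated libraries had no effect of the title start and the spread of the fit without the block. The simulated correlation and covariance thus come from a setting unlike the data.

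The combination against MMS alone asked what sorafenib did in cells that also met MMS. At 8 h the cytokine list had 1 rose and 6 fell of 25 measured, or 1 rose and 12 fell adjusted over the list alone, and 2 rose and 12 fell with the block (camera adjusted p = 2.44e-15). These included IL1B (log2 change -3.42 ± 0.29 SE, adjusted p = 0.000298), CSF3 (log2 change -1.88 ± 0.16 SE, adjusted p = 0.000298), IL1A (-1.84 ± 0.26), LIF (-0.61 ± 0.08) and CSF2 (-0.66 ± 0.12), all lower. Of the ERK list, 7 fell of 27 measured, or 14 fell adjusted over the list alone, and 13 fell with the block (camera adjusted p = 8.11e-20). These included DUSP4 (log2 change -0.75 ± 0.07 SE, adjusted p = 0.000402) and DUSP6 (-0.69 ± 0.09). Of the protease list, 5 fell of 25 measured, or 9 fell adjusted over the list alone, and 1 rose and 14 fell with the block (camera adjusted p = 1.33e-10). These included MMP3 (-3.18 ± 0.41), MMP1 (-2.59 ± 0.46) and PLAT (-1.27 ± 0.20). Of the immediate early list, 3 fell of 28 measured, or 12 fell adjusted over the list alone, and 1 rose and 12 fell with the block (camera adjusted p = 4.07e-13, adjusted p = 0.0796 with an estimated correlation). These included FOS (-1.90 ± 0.28), DUSP1 (-1.02 ± 0.15) and KLF6 (-0.84 ± 0.15). Of the NF-kB list, 2 fell of 26 measured, or 3 rose and 4 fell adjusted over the list alone, and 5 rose and 5 fell with the block (camera adjusted p = 0.939). These included PTGS2 (-2.09 ± 0.41). ARC (-3.53 ± 0.47) fell, to 1.28 CPM against 14.8. The inhibitors of differentiation ID1 (1.93 ± 0.33) and ID3 (1.78 ± 0.25) and the interferon-induced XAF1 (1.87 ± 0.27) rose, with a highest adjusted p of 0.0417 among the named genes. Of the angiogenic list, 1 fell of 32 measured, or 1 fell adjusted over the list alone, and 8 fell with the block (camera adjusted p = 0.0437, adjusted p = 0.123 with an estimated correlation). These included HBEGF (-0.65 ± 0.08). IL8 (-1.09 ± 0.23, adjusted p = 0.0667, and 5.03e-06 with the block), IL6 (-0.43 ± 0.20, adjusted p = 0.363) and VEGFA (-0.25 ± 0.18, adjusted p = 0.601) did not pass. Higher by camera were the interferon (camera adjusted p = 0.000105, adjusted p = 0.134 with an estimated correlation), replication (camera adjusted p = 0.00073, adjusted p = 0.427 with an estimated correlation), ATF4 (camera adjusted p = 0.0171, adjusted p = 0.515 with an estimated correlation), cholesterol (camera adjusted p = 0.029, adjusted p = 0.515 with an estimated correlation) and luminal lists (camera adjusted p = 0.0481, adjusted p = 0.21 with an estimated correlation, adjusted p = 0.0647 with the block). The histone list had camera adjusted p = 0.508, adjusted p = 0.0206 with the block.

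At 8 h 87 genes passed, 31 higher and 56 lower, 1326 with the block, 29 with only the 4 libraries compared, 356 with DESeq2 and 139 without a filter. The count was 11 without MMS replicate 1, 19 without combination replicate 1, 15 without MMS replicate 2 and 644 without combination replicate 2. Of 26 named genes past the test, IL1B, CSF3 and DUSP4 passed without each library in turn. IL1A, LIF, CSF2, DUSP6, MMP1, PLAT, FOS, DUSP1, KLF6, PTGS2, ID1, ID3, XAF1 and HBEGF did not pass without MMS replicate 1 (adjusted p from 0.0552 to 0.284). IL1A, CSF2, MMP3, MMP1, PLAT, FOS, KLF6, PTGS2, ARC, ID1 and ID3 did not pass without combination replicate 1 (adjusted p from 0.1 to 0.343). IL1A, LIF, CSF2, MMP1, PLAT, FOS, DUSP1, KLF6, PTGS2, ARC, ID1, ID3 and XAF1 did not pass without MMS replicate 2 (adjusted p from 0.0602 to 0.212). PTGS2 did not pass without combination replicate 2 (adjusted p = 0.0784).

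At 24 h the combination stood below MMS alone for fewer called genes. In the cytokine list, 4 fell of 25 measured, or 9 fell adjusted over the list alone, and 11 fell with the block (camera adjusted p = 2.85e-29). These included CSF3 (log2 change -2.14 ± 0.17 SE, adjusted p = 0.000139), IL1B (log2 change -3.21 ± 0.29 SE, adjusted p = 0.000539), IL1A (-2.20 ± 0.28) and IL11 (-1.24 ± 0.20). In the ERK list, 4 fell of 27 measured, or 12 fell adjusted over the list alone, and 12 fell with the block (camera adjusted p = 1.75e-37). These included DUSP4 (log2 change -0.99 ± 0.07 SE, adjusted p = 9.72e-05), DUSP6 (-0.90 ± 0.09) and PHLDA1 (-0.83 ± 0.13). In the protease list, 2 fell of 25 measured, or 1 rose and 6 fell adjusted over the list alone, and 2 rose and 8 fell with the block (camera adjusted p = 7.99e-09). These included MMP3 (-2.55 ± 0.39) and PLAT (-1.26 ± 0.20). In the angiogenic list, 1 fell of 32 measured, or 2 fell adjusted over the list alone, and 6 fell with the block (camera adjusted p = 6.49e-06). These included HBEGF (-0.53 ± 0.08). Of the metallothionein list, 1 fell of 7 measured, or 3 fell adjusted over the list alone, and 2 fell with the block (camera adjusted p = 1.42e-07). These included MT2A (-0.84 ± 0.12). The rises were the proteoglycan SDC2 (0.77 ± 0.11) and SEL1L3 (1.01 ± 0.16), and the highest adjusted p of the named genes was 0.0463. VEGFA (-0.81 ± 0.18, adjusted p = 0.178, and 0.000179 with the block), IL8 (-0.92 ± 0.23, adjusted p = 0.29, and 6.77e-05 with the block) and IL6 (-0.52 ± 0.20, adjusted p = 0.858) did not pass. Camera also called lower the immediate early (camera adjusted p = 2.83e-08, adjusted p = 0.134 with an estimated correlation) and histone lists (median -0.48, camera adjusted p = 0.00969, adjusted p = 0.522 with an estimated correlation), and higher the interferon (camera adjusted p = 0.00381, adjusted p = 0.269 with an estimated correlation) and luminal lists (camera adjusted p = 0.0209, adjusted p = 0.134 with an estimated correlation, adjusted p = 0.0576 with the block). In all 17 genes passed, 2 higher and 15 lower, 283 with the block, 5 with only the 4 libraries compared, 86 with DESeq2 and 43 without a filter. The count was 6 without MMS replicate 1, 3 without combination replicate 1, 4 without MMS replicate 2 and 3 without combination replicate 2. Of 13 named genes past the test, IL1B, CSF3 and DUSP4 passed without each library in turn. IL11, PHLDA1, MMP3, HBEGF, MT2A, SDC2 and SEL1L3 did not pass without MMS replicate 1 (adjusted p from 0.0628 to 0.277). IL1A, IL11, DUSP6, PHLDA1, MMP3, PLAT, HBEGF, MT2A, SDC2 and SEL1L3 did not pass without combination replicate 1 (adjusted p from 0.0504 to 0.361) or without combination replicate 2 (adjusted p from 0.071 to 0.342). IL1A, IL11, PHLDA1, MMP3, PLAT, HBEGF, MT2A, SDC2 and SEL1L3 did not pass without MMS replicate 2 (adjusted p from 0.0725 to 0.203).

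The sorafenib effect without MMS and the sorafenib effect with MMS, which share no library, had a correlation across genes of 0.44 at 8 h and 0.45 at 24 h. Of the 55 genes called for sorafenib alone at 8 h, 55 had the same direction in the combination against MMS, and of the 114 at 24 h, 113. The test of the difference between both effects called 0 genes at 8 h with edgeR, 7 with the block and 1 with DESeq2. At an unadjusted p under 0.05 the test gave 505 genes with edgeR, and 1267 with the block. Without combination 8 h replicate 2 it called 28. The 7 genes called with the block were chosen after their values were seen, and none passed without the block. In the blocked fit VEGFA was above 0 (1.01 ± 0.15, adjusted p = 0.0107). Below 0 in that fit were KLF6 (-0.88 ± 0.11, adjusted p = 0.00241), DUSP1 (-0.74 ± 0.12, adjusted p = 0.0216) and AKAP12 (-0.87 ± 0.14, adjusted p = 0.0216). So were ADAMTS1 (-1.09 ± 0.17, adjusted p = 0.0216), INHBA (-0.75 ± 0.12, adjusted p = 0.0216) and TFPI2 (-0.64 ± 0.11, adjusted p = 0.0222). Without the block the SE was 0.51 for ADAMTS1, 0.37 for INHBA and 0.44 for TFPI2. At 24 h edgeR called 0, with 304 at an unadjusted p under 0.05, 4 with the block, 1 with DESeq2 and 1 without a filter. The 4 genes called with the block were also chosen after their values were seen. In the blocked fit they were DUSP6 (0.98 ± 0.10, adjusted p = 0.000161), LPXN (0.72 ± 0.11, adjusted p = 0.0145), CST1 (1.32 ± 0.22, adjusted p = 0.0341) and the unnamed locus LOC647979 (-0.70 ± 0.10, adjusted p = 0.0141). Without the block the SE was 0.39 for LPXN and 1.21 for CST1.

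**Figure D3:**
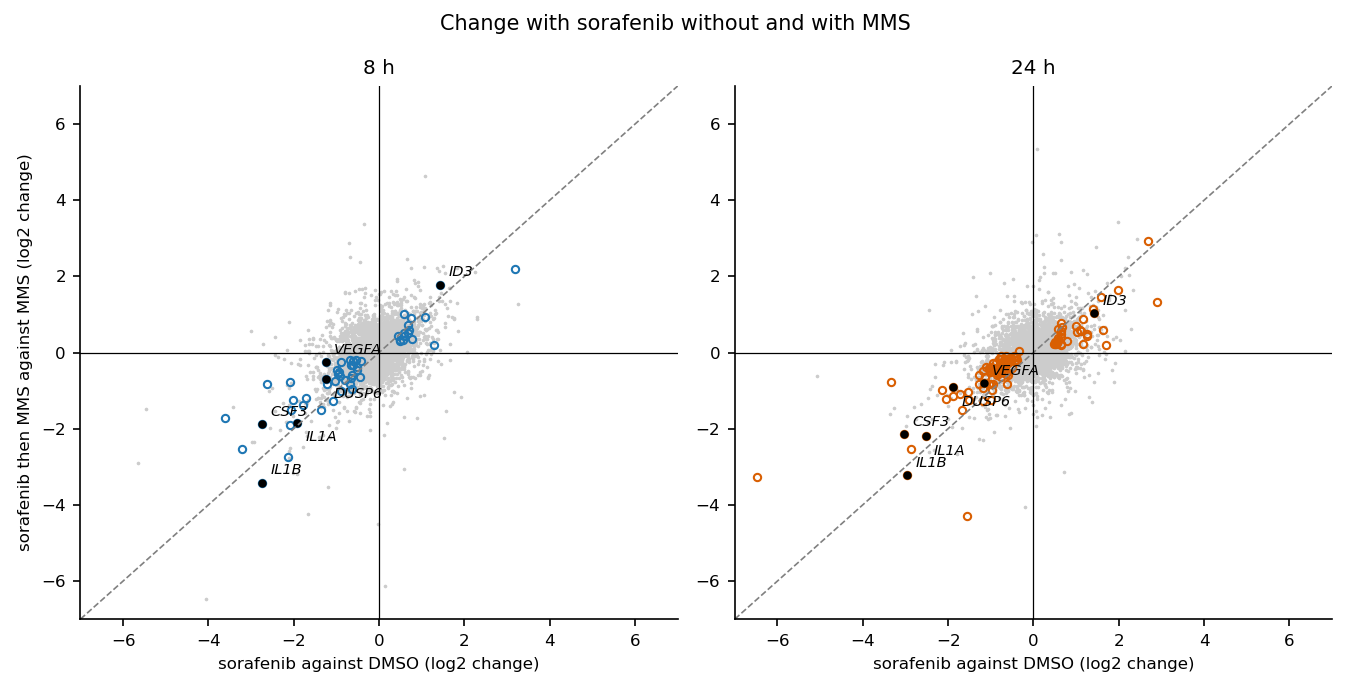
Log2 change with sorafenib against DMSO (horizontal axis) and with the combination against MMS (vertical axis) at 8 h and 24 h, 1 grey point per gene, open circles for the 55 and 114 genes called for sorafenib alone, black points for 6 named genes and the dashed line where both are equal. The called genes lie on the same side of 0 on both axes at 8 h, and 113 of 114 do at 24 h, while VEGFA at 8 h is at -1.25 on the horizontal and -0.25 on the vertical axis.

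Untreated cells also changed between the times. In DMSO at 24 h against 8 h the mTORC1 inhibitor DDIT4 stood at 226 CPM against 79.9 (adjusted p = 0.0241). The MYC antagonist MXI1 (log2 change 0.88 ± 0.12 SE, adjusted p = 0.0247) and BTN3A1 (0.87 ± 0.11) were higher, and THBS1 (log2 change -0.99 ± 0.11 SE, adjusted p = 0.00647), the chaperone HSPA8 (-0.70 ± 0.08), asparagine synthetase ASNS (-1.61 ± 0.24) and the tRNA ligase GARS (-0.73 ± 0.11) lower. In all 92 genes passed, 51 higher and 41 lower, 1902 with the block, 527 with DESeq2, 166 at a mean count of at least 50, and with only the 4 libraries compared 0. The count was 0 without DMSO 8 h replicate 1, 10 without DMSO 24 h replicate 1, 0 without DMSO 8 h replicate 2 and 0 without DMSO 24 h replicate 2. DDIT4, MXI1, BTN3A1, THBS1, HSPA8, ASNS and GARS did not pass without DMSO 8 h replicate 1 (adjusted p from 0.08 to 0.176) or without DMSO 8 h replicate 2 (adjusted p from 0.052 to 0.18) or without DMSO 24 h replicate 2 (adjusted p from 0.0613 to 0.188). BTN3A1 and GARS did not pass without DMSO 24 h replicate 1 (adjusted p = 0.0593 each).

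**Figure D4:**
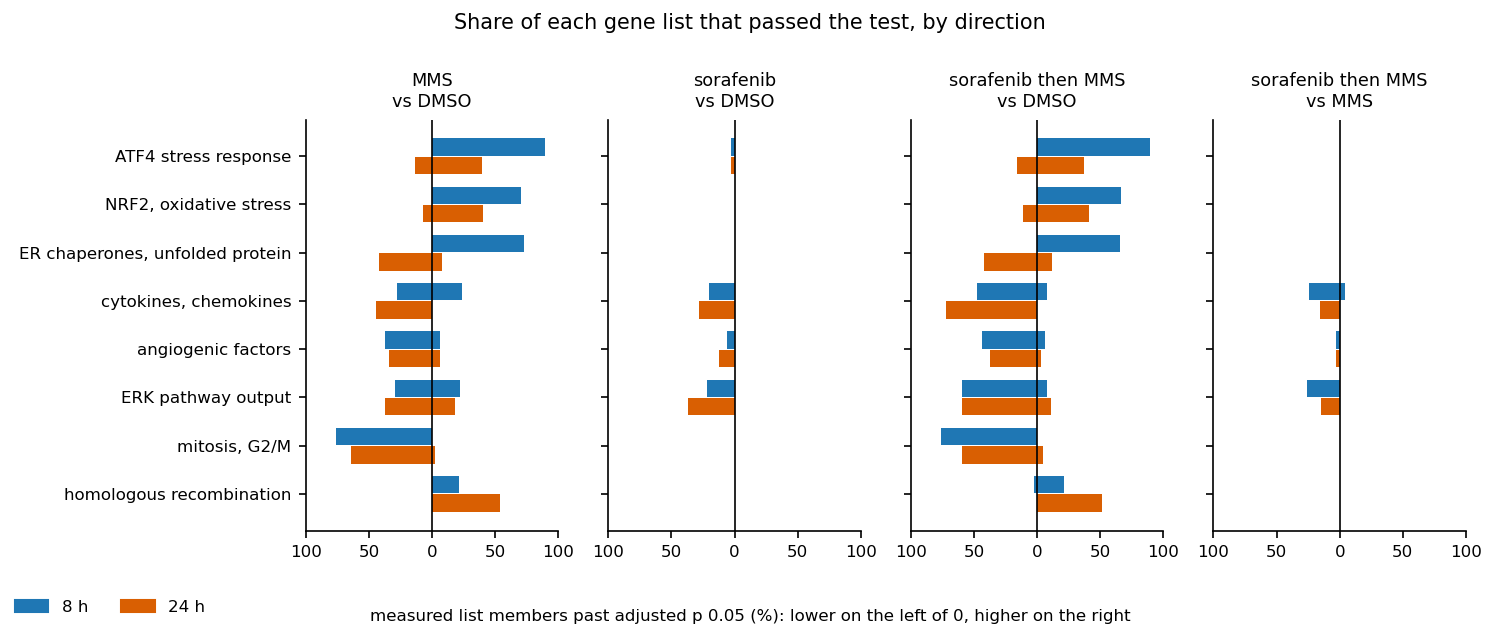
Share (%) of the measured members of 8 gene lists that passed edgeR's test, higher members to the right of 0 and lower members to the left, for 4 comparisons at 8 h (blue) and 24 h (orange). With MMS 34 of 38 ATF4 members were higher at 8 h, and with the combination 18 of 25 cytokine members were lower at 24 h.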

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

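The tests of scaling, gene span and GC content were written before their results, and those on cytokines and VEGFA after the results were seen. Between the times the effect differed, by a test of the difference, for 1273 genes under MMS and 1507 under the combination. Under MMS the differences (24 h less 8 h) were ZNF238 1.67, RIN2 1.46, THBS1 1.59 (mostly from DMSO), SPC24 1.79, SLC45A3 1.52, HSPA5 -2.67, SESN2 -2.85, XBP1 -2.21, HERPUD1 -2.70 and DDIT4 -3.73. With the combination they were ZNF238 1.37, STARD13 1.18, THBS1 1.53, MYBL1 1.21, CSF2 1.39, SESN2 -3.02, XBP1 -2.32, HERPUD1 -2.90, HSPA5 -2.49 and DDIT4 -4.77. Of reads outside the gene counts, the ambiguous share was 1.17% with MMS at 24 h and the share in no gene 7.66% with the combination at 24 h, each above its DMSO libraries.

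Cytokine genes with log2 changes above 0 at 8 h of MMS and below 0 at 24 h formed 1 pattern of 8 members chosen after their values were seen: IL1A, IL6, IL8 and CSF3, which passed at both times (with some libraries left out not IL1A and IL6 at 8 h nor IL6 and IL8 at 24 h), CXCL2 and CXCL3, which passed at 8 h alone, IL1B, which passed at 24 h alone, and LIF, which passed at neither. A median 29.3% of the difference (interquartile range 13.1 to 47.5) came from higher mean DMSO levels at 24 h, between the limits set for and against drift of the controls, with 7.51% for CXCL3 and 8.00% for CXCL2 but 50.77% for IL1B and 74.85% for CSF3. The MMS libraries themselves were lower at 24 h than at 8 h, IL8 at 419 against 1342 CPM and CXCL2 at 25.9 against 156, so that drift was part of the difference of these 2 genes at most, and how much it gave the others stays open. In both title starts 75% of the members changed sign, not IL1B and CXCL3, which left a difference between the starts undecided. A time course of MMS is the biological alternative.

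VEGFA was lower with sorafenib alone at 8 h but not with sorafenib followed by MMS against MMS, an interaction of 1.00 ± 0.25 that did not pass (adjusted p = 1.00, and 0.0107 with the block). Without each library in turn it stayed between 0.82 and 1.21, which speaks against a single deviating library. Sorafenib alone at 24 h left VEGFA at -1.16 (-1.52 to -0.80), which speaks against the longer exposure of the combination. At 24 h the interaction was 0.35 ± 0.25 (adjusted p = 1.00, and 0.653 with the block), and an effect of MMS on the response to sorafenib at 8 h remains a hypothesis.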

How the results depend on the processing

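All settings below were planned, and none was chosen after a result was seen. RLE factors kept all 14 counts of genes within 1.5 times, with median shifts under 0.1. With the block counts moved to 6035 and 6730 (MMS, 8 h and 24 h), 702 and 1001 (sorafenib), 5514 and 7043 (combination against DMSO), 1326 and 283 (combination against MMS), 7 and 4 (interaction), 3562 (MMS between times), 4016 (combination between times) and 1902 (DMSO), and shared calls of MMS and the combination to 4197 and 5766. The block raised 77 of 670 gene values past the threshold, ended none and, beyond the calls of lists given in the report, changed no other call. DESeq2 gave 176 and 296 (sorafenib), 356 and 86 (combination against MMS), 1 and 1 (interaction) and 527 (DMSO). With only the libraries compared, which leaves fewer samples, counts were 2714 (MMS, 24 h), 4 and 5 (sorafenib), 1948 (combination against DMSO, 8 h), 29 and 5 (combination against MMS), 776 and 441 (MMS and combination between times) and 0 (DMSO; edgeR gave 92 with all libraries). Without a filter they were 101 (sorafenib, 8 h), 139 and 43 (combination against MMS) and 1 (interaction, 24 h), and at a mean count of at least 50, 166 (DMSO). The cause of the other moves was not tested. With an estimated correlation the lists called fell from 13, 18, 9, 11, 14, 18, 10 and 9 to 5, 1, 4, 4, 6, 5, 3 and 5 in the order of MMS, sorafenib, combination against DMSO and combination against MMS, 8 h before 24 h. In the same order fry's directional test called 14, 18, 4, 7, 15, 18, 7 and 5, and its test without direction 23, 23, 13, 14, 23, 23, 14 and 6. Without MMS 8 h replicate 2 camera called 6 lists instead of 10 in the combination against MMS at 8 h.

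Leaving out a library gave 2272 to 2619 and 2466 to 3492 (MMS), 5 to 17 and 12 to 75 (sorafenib), 2121 to 3179 and 2940 to 3732 (combination against DMSO), 11 to 644 and 3 to 6 (combination against MMS), 0 to 28 (interaction, 8 h), 577 to 917 (MMS between times), 614 to 1610 (combination between times) and 0 to 10 (DMSO). The interaction at 24 h and the sorafenib effect between times stayed at 0 by edgeR. Of 2760 such gene values 2366 kept their side, 372 lost the call, 16 gained it and 6, none called, changed sign: VEGFA -0.0548 to 0.301 (MMS, 8 h) and -0.298 to 0.0529 (combination, 8 h), IL6 -0.294 to 0.00365 (sorafenib, 8 h) and -0.120 to 0.348 (24 h), LUM -0.155 to 1.01 (combination, 8 h) and HIST1H1E -0.900 to 0.0658 (combination against MMS, 24 h). With sorafenib 4 of 21 named genes at 8 h and 7 of 33 at 24 h kept their call throughout, and with the combination against MMS 3 of 26 and 3 of 13. Of simulated 1.5-fold changes 49.3% were recovered, and 85.1% with the block. Those counts were drawn from the blocked fit, with changes in genes with a mean count of at least 50 only.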

Other observations

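The genes of this paragraph were chosen after their values were seen. Stromelysin MMP3 (2.86 ± 0.40) rose with MMS at 8 h and MMP3 (3.52 ± 0.42) at 24 h. With sorafenib before MMS it was lower than with MMS alone at 8 h, MMP3 (-3.18 ± 0.41), and at 24 h, MMP3 (-2.55 ± 0.39). The hyaluronidase gene KIAA1199 moved in opposite directions, -4.43 ± 0.30 with MMS and 1.64 ± 0.23 with sorafenib at 24 h. In the combination against MMS at 8 h MMP3 did not pass without combination replicate 1 (adjusted p = 0.1). At 24 h MMP3 did not pass without MMS replicate 1 (adjusted p = 0.106) or without combination replicate 1 (adjusted p = 0.319) or without MMS replicate 2 (adjusted p = 0.15) or without combination replicate 2 (adjusted p = 0.0725). For sorafenib at 24 h KIAA1199 did not pass without DMSO replicate 1 (adjusted p = 0.0684) or without sorafenib replicate 1 (adjusted p = 0.0867).

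More genes fell than rose over 2-fold with MMS at 24 h (840 against 134), and the tests of this pattern were written before their results. The genes that fell at 24 h spanned more of the genome: a median of 64.5 kb against 31.3 kb for unchanged and 10.7 kb for genes that rose, in a later build than the reads' own. Against unchanged genes of like expression the ratio was 2.30 (1.95 to 2.68). Scaling stays open, since other factors differed little (at least 81.5% falls). Removing the trend on GC content still left 78.6% falls. At 8 h the medians were 68.1, 31.2 and 17.5 kb with 57.3% falls, no test removed a trend on span, and loss of transcripts from long genes remains a hypothesis found and tested on the same data.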
